A study of Mus musculus with 6 samples.

How the data were processed

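ChIRP-seq of LncMyoD was done in differentiated C57BL/6 mouse myotubes, per the labels' protocols. Nuclei were sonicated, RNA-bound DNA was captured with biotin-labelled DNA probes, and libraries were made by tagmentation with the TruePrep V2 kit and sequenced as paired 100-base reads on a DNBSEQ-G400. The 6 samples were grouped by their titles into an odd probe pool, an even probe pool and input, with 2 replicates each.

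The deposited files were 2 peak lists in the narrowPeak layout, without headers. The submitters' processing notes name Bowtie2 2.3.2, Picard 2.9.2, MACS2 2.1.1 and the build mm10, with no order or parameters. Which libraries were the treatment and the control of each call, whether odd and even libraries were merged, and the threshold are not given in the sources used here. The description label that matches each list's name is shared by the odd, even and input samples of a replicate, so each list was treated as the authors' pooled list of that replicate, with no SD or n of its own. The fold enrichment at each summit is the authors' ratio to the background that the caller estimated. The p and q of each peak were deposited as −log10 values, and the lowest −log10 q was 1.345 in replicate 1 and 1.324 in replicate 2. The summit position was deposited by the authors in bp from the start of the peak. Tagmentation has sequence preferences, and the lists keep no reads from which these could be corrected. Depth is unknown except for the step of the fold values: folds that are whole multiples of a smallest step give the background pileup as the inverse of the step minus 1, if the caller added 1 to both pileups. This held within 0.01 for 67.5% of the peaks of replicate 1 and 74.3% of those of replicate 2. No interval or floor that needs read depth is given.

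Peaks overlapping by at least 1 bp were called partnered, and a shared region was the union of overlapping peaks holding at least 1 of each list. Chance overlap came from 1000 circular rotations, in which all peaks of a chromosome moved by the same random offset along the span covered by peaks and genes. The p for overlap was one-sided and the p for features and gene counts two-sided, with smallest possible values of 0.001 and 0.002. Chance overlap by steps of 10% of q came from 100 rotations. A region's place is its order by the mean, over both lists, of the percentile of −log10 q of its best peak. Genes came from a RefSeq table of assembly GRCm38.p6, the assembly behind mm10, with 21887 protein-coding genes on 21 chromosomes. Peaks on unplaced scaffolds entered the overlap and not the gene comparisons.

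The comparisons, 11 gene lists and alternatives were fixed before the data were examined. The gene table holds gene starts and ends without strand, exons or sequence, so several planned steps were changed or left out. Windows of 5 kb around transcription start sites became windows of 5 kb either side of both gene ends. Promoter, UTR, coding exon and intron classes became 3 classes: within 1 kb of a gene end, elsewhere in a protein-coding gene, and outside. Motif tests at summits were not run. LncMyoD is not named in the table, so the interval between Otog and Kcnc1, which holds Myod1, was described instead.

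Named genes followed a fixed rule. Some results that it names are not reported here. It takes all 26 myogenic regulators, the 4 members of every other list whose best shared region within 5 kb had the highest mean percentile of −log10 q, the genes nearest to the 10 strongest shared regions, and LncMyoD, Myod1, Igf2bp1, Igf2bp2, Igf2bp3, Nras and Myc. Otog, Gm45923 and Kcnc1 as neighbours of Myod1, and Eno3, Phka1 and Ak1 as members without a region, were named after their values were seen. Gene lists were compared with all other protein-coding genes by two-sided Fisher's exact tests, and shares carry 95% exact (Clopper-Pearson) intervals.

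The alternatives were −log10 q of at least 5, fold of at least 5, the 10000 peaks with the highest −log10 q, a reciprocal overlap of 50%, summits within 200 bp, autosomes alone, removal of the 1% of peaks with the highest fold, either list alone, other windows, and a local shift of each peak or region by 100 kb to 1 Mb. Alternatives added after the data were seen were 10000 random gene lists matched on gene length, the local shift for genes near regions and for gene classes, the 10000 strongest peaks for features, and partnered peaks of replicate 1 at several thresholds, among them −log10 q of at least 20 and the 30000 strongest peaks. Random lists matched on GC content were not run.

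The overlap code was tested on simulated data: with 50% of 50000 peaks planted in both lists it found 50.9% partnered, and with none planted the ratio to rotation was 0.995. Of 200 simulated lists of 26 genes with regions at 85% of members, 91.0% passed an unadjusted 0.05, against 6.0% of 200 unchanged lists. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used.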

Results

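The data came from mouse myotubes in which DNA bound by the long non-coding RNA LncMyoD was isolated by ChIRP, a method that captures an RNA and the chromatin attached to it with biotin-labelled probes. Primary C57BL/6 myoblasts were kept in 2% horse serum for 2 days to form myotubes. The 6 samples fell into 3 groups of 2 replicates: an odd-numbered probe pool, an even-numbered probe pool and input DNA. Odd and even pools tile the same RNA with different probes, so that a probe's own off-target DNA appears in one pool and not in the other. The deposited results were 2 peak lists, 1 per replicate, in mm10 coordinates. The labels give each list's name to the odd, even and input samples of a replicate alike, so the pools could not be compared with each other or with input here. The labels do not say whether the replicates were separate cultures, and the spread between the lists may be technical.

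The list of replicate 1 held 157214 peaks over 84.9 Mb, with a median width of 384 bp. The list of replicate 2 held 179630 peaks over 99.8 Mb, with a median width of 394 bp. Fold enrichment and q were the authors' values for each peak and are used only within a list. The median fold was 8.08 in replicate 1 and 8.11 in replicate 2, and the highest folds were 117 and 120. Sequencing depth was not given in the sources used here. Most fold values (67.5% and 74.3%, within 0.01 of a whole step) were whole multiples of 0.367 in replicate 1 and 0.309 in replicate 2, which corresponds to a background of about 1.72 and 2.24 overlapping fragments under the caller's added count of 1.

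The comparison of the replicates asked which binding sites were found in both. Of the peaks of replicate 1, 105647 (67.2%) overlapped a peak of replicate 2 by at least 1 bp. Of the peaks of replicate 2, 103908 (57.8%) overlapped a peak of replicate 1. Together they formed 97493 shared regions with a median width of 749 bp and a total of 88.2 Mb. When the other list was rotated along each chromosome, the overlap was 7.18% ± 0.075 (SD over 1000 rotations) and 6.26% ± 0.065. The observed shares were 9.36 and 9.24 times these values (one-sided permutation p = 0.001 for each, the smallest that 1000 rotations can give). No list from input or from probes against an unrelated RNA was analysed here, so the rotation measures chance placement and not the background of the capture.

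Overlap rose with the strength of a peak. In the weakest 10% of each list, those with the highest q, 38.0% of the peaks of replicate 1 and 27.9% of those of replicate 2 had a partner. In the strongest 10%, those with the lowest q, the shares were 94.9% and 92.9%, as the plot of partnered peaks by q shows. The strongest 10% were also wider (median 1097 bp against 237 bp in replicate 1, 1180 bp against 236 bp in replicate 2). Against rotation, the ratio in replicate 1 rose from 6.77 in the weakest 10% to at most 10.6 and was 8.56 in the strongest 10%. In replicate 2 these ratios were 5.79, 10.7 and 9.41. Peaks of replicate 1 with a partner had a median fold of 10.4, against 5.73 for those without. In replicate 2 the medians were 11.4 and 5.87.

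**Figure D1:**
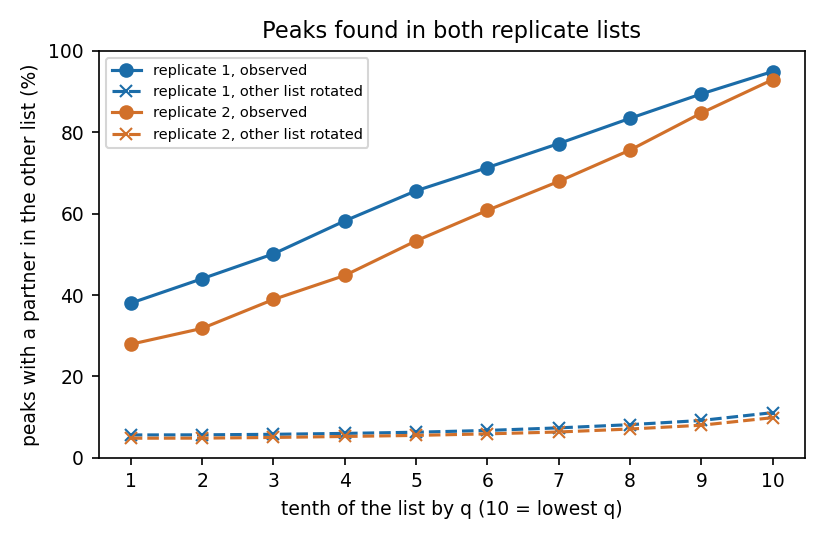
Percent of peaks that overlapped a peak of the other list (vertical axis) in steps of 10% of a list by q (horizontal axis, 10 = lowest q), observed (solid lines) and as the mean after rotation of the other list (dashed lines, 100 rotations). The share rose from 38.0% to 94.9% in replicate 1 and from 27.9% to 92.9% in replicate 2.

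LncMyoD is encoded next to Myod1, the gene of the muscle-determining transcription factor MyoD, and the locus of the captured RNA is the usual positive control of a ChIRP experiment. A pair of shared regions between Otog and Myod1 ranked among the strongest in the genome. The first, on chromosome 7 from 46344299 to 46347749, lay 28725 bp from Myod1 and held the peaks of rank 13 by q in replicate 1 (109-fold) and 26 in replicate 2 (90.2-fold). The next, from 46348808 to 46353059, lay 23415 bp from Myod1 and ranked 112 (92.9-fold) and 108 (80.0-fold). They took places 15 and 69 among the 97115 shared regions on the assembled chromosomes, ordered by mean percentile of −log10 q. They were 3451 and 4252 bp wide, and 0.56% of shared regions were wider than 3000 bp. The gene table used here does not name LncMyoD, so the overlap of these regions with its exons was not measured. Capture of this DNA through the RNA and directly by the probes could not be told apart from the 2 peak lists.

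Elsewhere in this interval the signal was lower. Myod1 itself (46376474 to 46379092) held a shared region from 46376544 to 46377109, with folds of 10.7 and 7.72 and place 58795. Gm45923, a non-coding RNA gene from 46371403 to 46372492, overlapped no peak of either list. Another shared region, from 46347861 to 46348387, had folds of 3.67 and 9.88. Replicate 2 also had peaks of 32.1-fold (46320677 to 46321527) and 18.8-fold (46392971 to 46393383) without a partner in replicate 1. In all, the 84784 bp between Otog and Kcnc1 held 7 peaks of replicate 1 and 15 of replicate 2.

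**Figure D2:**
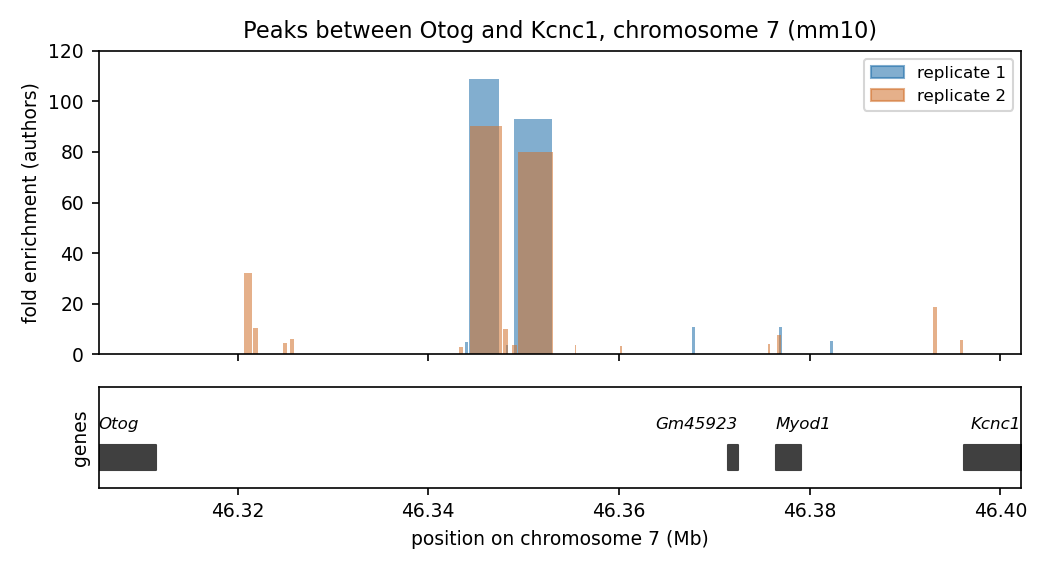
Peaks of replicate 1 (blue) and replicate 2 (orange) between Otog and Kcnc1, drawn at their width on chromosome 7 (mm10, Mb) with the authors' fold enrichment as height, above the annotated genes of the interval. The peaks of 109-fold and 92.9-fold in replicate 1 lie over peaks of 90.2-fold and 80.0-fold in replicate 2.

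None of the genes nearest to the 10 strongest shared regions was in a fixed gene list. The first by mean percentile of −log10 q lay inside Gm17266 on chromosome 18, from 84829323 to 84834570, with folds of 117 and 120 and rank 1 in both lists. The next lay between genes on chromosome 1 (171489087 to 171492186, 116-fold and 107-fold), 10862 bp from the snRNA gene LOC115487699 and 11292 bp from Alyref2, its nearest protein-coding gene. It was followed by a region overlapping Podnl1 on chromosome 8 (84122887 to 84126981, 95.1-fold and 107-fold). A region 1063 bp from Rnf223 on chromosome 4 had folds of 114 and 70.9. A region 4762 bp from Gdf3, the gene of a TGF-beta family ligand, had folds of 84.3 and 83.3. Regions inside Efr3b (110-fold and 87.6-fold) and inside Myh14, a non-muscle myosin heavy chain gene (111-fold and 82.4-fold), took places 6 and 10. The remaining 3 of the first 10 lay nearest to the pseudogene Gm9652 (116-fold and 99.8-fold) and to the non-coding RNA genes Gm16863 (111-fold and 76.4-fold) and Gm38827 (88.4-fold and 71.8-fold).

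Across the genome, shared regions lay near the ends of protein-coding genes more often than rotated regions did. Of 97115 regions, 4.68% had their midpoint within 1 kb of either end of such a gene, against 3.02% ± 0.069 after rotation (ratio 1.55). A further 38.0% lay elsewhere in a protein-coding gene, against 37.5% ± 0.31 (ratio 1.01). The remaining 57.4% lay outside protein-coding genes, against 59.5% ± 0.34 (ratio 0.965). The two-sided permutation p, Benjamini-Hochberg adjusted over the 3 classes, was 0.003 for gene ends and for regions outside genes, and 0.16 for the rest of genes. When regions were moved by 100 kb to 1 Mb, which keeps the regional density, the ratio at gene ends was 1.32, that elsewhere in genes became 0.95 and that outside genes turned to 1.02. The gene table has no strand, so starts and ends of genes were not told apart.

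Of 21887 protein-coding genes, 12510 (57.2%) had a shared region within 5 kb of either end. Rotation gave 47.9% (10483 ± 129 genes), a ratio of 1.19 (two-sided permutation p = 0.002, the smallest possible). The ratio was 1.04 against regions moved locally (permutation p = 0.002). With a window of 1 kb the count was 5901 genes, a ratio of 1.46.

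Among 26 regulators of muscle differentiation, 16 had a shared region within 5 kb (61.5%, 95% exact binomial interval 40.6 to 79.8%), against 57.2% of other genes (odds ratio 1.2, Fisher's exact adjusted p = 0.77). Counted in the list of replicate 2 alone, 24 of the 26 did (92.3% against 74.3%, odds ratio 4.15, Fisher's exact p = 0.041, adjusted p = 0.45), and in that of replicate 1 alone 20 did (76.9% against 68.5%, odds ratio 1.53, exact p = 0.41). Mymx, which encodes the fusion peptide myomixer, had 4 shared regions, the strongest at 88.5-fold and 72.9-fold over one of its ends (chromosome 17, 45599720 to 45601659). Mymk, the gene of the other myoblast fusion protein myomaker, had 2, the stronger at 38.6-fold and 32.1-fold. The RNA-binding protein gene Rbm24 had 3 regions, reaching 66.8-fold and 52.2-fold. Eya1, a transcriptional cofactor gene, had a region of 52.9-fold and 61.5-fold. Among transcription factors of the myogenic lineage, the best regions were at Pax3 (34.5-fold and 28.7-fold), Myf5 (31.8-fold and 20.4-fold) and Myog (25.3-fold and 10.5-fold). The MEF2 genes Mef2a, Mef2d and Mef2c had 1 region each, with folds of 12.9 and 13.9, 20.6 and 9.12, and 6.98 and 4.63. The bHLH inhibitors Id3 (25.3-fold and 32.7-fold) and Id2 (14.3-fold and 7.20-fold) and the cell cycle inhibitors Cdkn1c (17.3-fold and 19.8-fold) and Cdkn1a (12.1-fold and 10.8-fold) also had 1 region each. No shared region lay within 5 kb of an end of Myf6, Pax7, Six4, Tcf3, Tcf12, Id1, Rb1, Smyd1, Runx1 or Klf5.

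Genes of the contractile apparatus and of muscle metabolism were counted in the same way, against 57.1% of other protein-coding genes for each list. Of 42 sarcomere genes, 26 (61.9%, interval 45.6 to 76.4%) had a shared region nearby, led by Mybpc1, which encodes slow myosin-binding protein C (45.1-fold and 74.0-fold), Actn2 (62.1-fold and 39.0-fold), the nebulin gene Neb (26.8-fold and 56.8-fold) and Mybph (30.9-fold and 26.2-fold). Of 26 genes of excitation-contraction coupling and the neuromuscular junction, 19 did (73.1%, interval 52.2 to 88.4%). They were led by the calsequestrin gene Casq2 (65.1-fold and 72.4-fold), the acetylcholine receptor gene Chrnb1 (39.0-fold and 54.7-fold), the calcium release channel gene Ryr1 (42.6-fold and 41.4-fold) and Sgca (37.5-fold and 43.2-fold). The muscle metabolism list had the highest share, 16 of 19 genes (84.2%, interval 60.4 to 96.6%). It was led by the myoglobin gene Mb (43.8-fold and 55-fold), Amd1 (41.3-fold and 17.2-fold), Ldha (25.3-fold and 23.8-fold) and Pgam2 (20.6-fold and 19.4-fold). Amd1 counts as a member by the fixed list, and its role in muscle metabolism was not examined.

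Gene lists of other cell types had shares from 40.9% to 81.2%. The list of blood genes had 13 of 16 members near a shared region (81.2%), led by Zap70 (40.4-fold and 67.0-fold), Itga2b (41.2-fold and 46.9-fold), Spi1 (24.6-fold and 34.8-fold) and Mpo (23.5-fold and 30.6-fold). The pluripotency list had 12 of 15 (80.0%), led by Prdm14 (19.8-fold and 44.2-fold), Lin28a (23.5-fold and 17.6-fold), Dnmt3l (18.9-fold and 13.4-fold) and Esrrb (14.1-fold and 20.1-fold). Hepatocyte genes had 14 of 20 (70.0%), led by Cyp3a11 (48.3-fold and 67.6-fold), Cps1 (34.9-fold and 45.7-fold), Fgb (25-fold and 34.0-fold) and Hpx (13.6-fold and 23.8-fold). Neuronal genes had 11 of 20 (55%), among them Grin1 (39.3-fold and 56.2-fold), Rbfox3 (32.0-fold and 43.2-fold) and Camk2a (26.8-fold and 20.1-fold). Markers of other cells of muscle tissue had the lowest share, 9 of 22 (40.9%, interval 20.7 to 63.6%), led by Csf1r (11-fold and 35.8-fold), Kdr (12.9-fold and 14.8-fold), Ptprc (8.08-fold and 14.5-fold) and Sox10 (20.6-fold and 6.49-fold).

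Cell cycle genes had 18 of 28 members near a shared region (64.3%), led by Ccnb2 (51.4-fold and 72.9-fold), Plk1 (42.6-fold and 36.1-fold), Aurkb (24.6-fold and 39.2-fold) and Cdk4 (36.0-fold and 21-fold). Ubiquitously expressed genes had 17 of 25 (68.0%), led by B2m (70.9-fold and 67.0-fold), Ywhaz (77.7-fold and 36.8-fold), Vcp (33.1-fold and 50.7-fold) and Polr2a (28.3-fold and 33.4-fold). None of the 11 lists differed from other protein-coding genes past an adjusted p of 0.05 (two-sided Fisher's exact test, Benjamini-Hochberg over the lists). Muscle metabolism was the only list past 0.05 before adjustment (odds ratio 4.0, Fisher's exact p = 0.019, adjusted p = 0.21), and its members without a shared region nearby were Eno3, Phka1 and Ak1. Its odds ratio was 2.94 in the list of replicate 2 alone (exact p = 0.19) and 2.45 in that of replicate 1 alone (exact p = 0.21), 1.06 over whole genes and 0.741 among the 10000 strongest peaks. A list of 15 to 42 genes gives wide intervals, as the plot of gene lists shows.

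**Figure D3:**
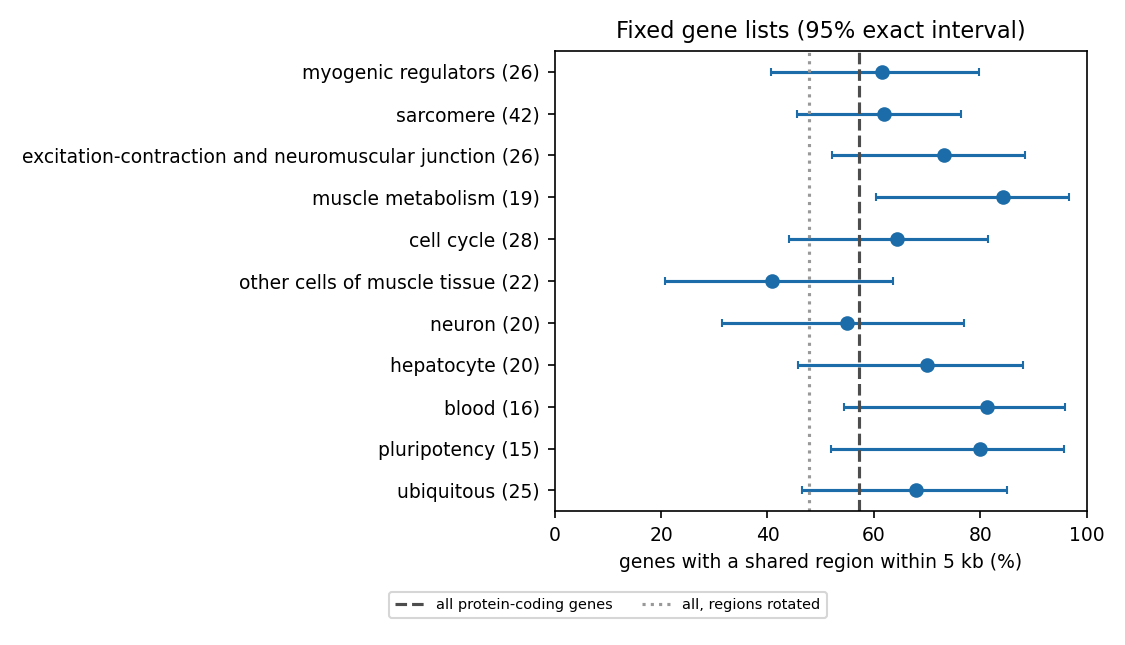
Percent of the genes of each fixed list (number of genes in brackets) with a shared region within 5 kb of either gene end, with 95% exact binomial intervals. The dashed line marks all protein-coding genes (57.2%) and the dotted line their mean after rotation of the regions (47.9%); muscle metabolism had the highest share (84.2%) and other cells of muscle tissue the lowest (40.9%).

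LncMyoD is known to bind Igf2bp2, an RNA-binding protein that promotes translation of Nras and Myc. No shared region lay within 5 kb of an end of Igf2bp2, Igf2bp1 or Nras. Igf2bp3 had a shared region of 27.2-fold and 40.8-fold, and Myc had a region of 9.95-fold and 14.8-fold on chromosome 15 (61985689 to 61987483), inside the gene. A shared region within 5 kb was found at 57.2% of all protein-coding genes. These regions concern DNA and do not bear on binding of the RNA to protein or on translation.

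Shared regions were denser on every autosome than on the sex chromosomes. The 19 autosomes held 38.2 ± 3.51 shared regions per Mb (mean and SD over autosomes), from 32.8 on chromosome 3 to 47.7 on chromosome 10. Chromosome X held 19.2 per Mb, 0.502 times the autosomal density, and chromosome Y 24.2. The median fold of peaks was 8.08 on X and on the autosomes in replicate 1, and 8.03 and 8.13 in replicate 2. This comparison was chosen after the data were seen.

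**Figure D4:**
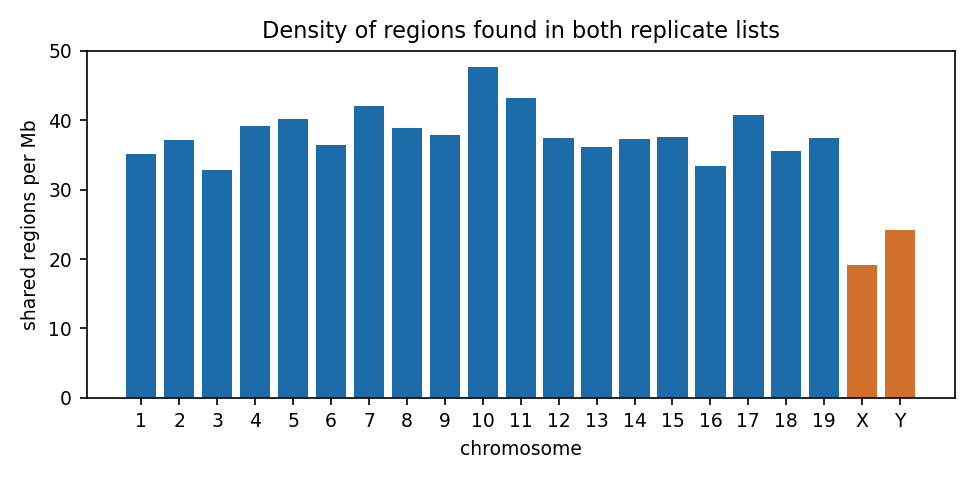
Shared regions per Mb (bars, vertical axis) on each chromosome (horizontal axis), over the span from the first to the last peak of either list; autosomes in blue, sex chromosomes in orange. Chromosome X (19.2) and chromosome Y (24.2) lie below the lowest autosome (32.8).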

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

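The tests of weak signal and of X peaks at 5-fold and 20-fold were chosen after the result was seen. Unplaced scaffolds lie outside the gene comparisons and still held peaks: 598 in the list of replicate 1 and 552 in that of replicate 2, forming 377 shared regions.

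Of the peaks of replicate 1, 32.8% had no partner in replicate 2, and 42.2% of the peaks of replicate 2 had none in replicate 1. Weak signal stays open: 92.9% of the strongest 10% of peaks, those with the lowest q, had a partner in the list with the lower share, but this value was known when its bound was set. Unpartnered peaks lay within 1 kb of a peak of the other list at least 2.74 times as often as after rotation (35.6% against 11.5% in replicate 1, 27.6% against 10.1% in replicate 2). Shifted borders may account for a part of these, but the ratio cannot tell them from distinct peaks beside a shared one. Rotation separates such neighbours as well. Most unpartnered peaks lay farther away, so shifted borders leave the larger part open. No biological explanation was tested, since both lists come from the same condition.

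Chromosome X had 0.502 times the autosomal density of shared regions, and 0.458 to 0.544 times that of peaks at equal fold thresholds of 5, 10 and 20. Lower gene density was argued against, because X was sparser both inside protein-coding genes (0.337 times) and outside them (0.574 times). A single X copy, taken to lower peak height by a factor of 2, was examined at shifted thresholds. X peaks of at least 10-fold were 1.18 and 1.07 times as dense as autosomal peaks of at least 20-fold. The ratios at 5-fold against 10-fold were 1.08 and 0.952. These ratios cannot decide the question, because fewer X peaks of unchanged height would also give values near 1. Autosomal density itself fell from 24.7 per Mb at 10-fold to 11.2 at 20-fold in replicate 1, and from 28.8 to 12.9 in replicate 2. At 20-fold against 40-fold the ratios were 1.86 and 1.93, above every autosome. These values argue against halved height for X peaks of at least 20-fold. Chromosome Y held 24.2 shared regions per Mb, so Y DNA may be present, but the placement of reads that match several sites is not given in the sources used here, and poorly mapping sequence and a true difference in binding were not tested.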

How the results depend on the processing

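The replicate lists overlapped above chance in every setting run for the overlap, with ratios from 8.55 to 59.8. The partnered shares of replicates 1 and 2, 67.2% and 57.8% by 1 bp, depended on the rule. They were 41.8% and 36.6% with a reciprocal overlap of 50%, and 48.9% and 42.8% with summits within 200 bp. The ratio of 59.8 came from the 10000 strongest peaks, where 65.7% of those of replicate 1 had a partner against 1.1% after rotation. Among the 10000 strongest peaks of each list the shared regions numbered 6437, and 1527 genes had one within 5 kb; fewer peaks entered by construction. With windows of 1 kb in place of 5 kb the gene count was 5901. The ratio of regions elsewhere in a protein-coding gene (1.01, not past the threshold) passed it with each list alone (1.02 to 1.04), among the 10000 strongest peaks (1.04, a setting added after the data were seen) and, in the other direction, after local shifts (0.95). The ratio at gene ends was 1.95 among the 10000 strongest peaks, against 1.55. The ratio outside genes reversed from 0.965 to 1.02 after local shifts; the cause was not tested. No gene list passed an adjusted p of 0.05 in any of the 17 other settings, 9 of them chosen after the data were seen (lowest 0.2), while 49 of 187 odds ratios lay on the other side of 1 from the main value. The adjusted p of muscle metabolism ranged from 0.21 to 1. In all, 251 alternative values of the reported results stayed on their side of the threshold or within 1.5 times the main count. They include all 187 gene list odds ratios, those 49 among them, which stayed only because no list passed in any setting. The count therefore says little about stability. A value that stayed could still change in size: the ratio of genes near a shared region fell from 1.19 to 1.04 after local shifts. No paired analysis was possible because each replicate has a single list for its odd, even and input samples. Motif tests, GC-matched lists and classes by strand or exon were not run, since no sequence or exons were used here. Read depth may limit the weakest peaks, which was not tested, and its size is not given in the sources used here.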

Other observations

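The gene classes, their local shifts and the set of other short genes were chosen after the data were seen, and the density tests after the low share of olfactory receptor genes was. Of 38 classes compared with rotation (14 gene types within 1 kb and 24 families by symbol within 5 kb), 11 lay above it and 2 below past an adjusted two-sided permutation p of 0.05. After local shifts 7 lay above and 3 below. A region anywhere inside a gene counted here as well, so the shares depend on gene length. Ribosomal RNA genes stood highest, with 49 of 63 near a shared region (77.8% against 10.3%, ratio 7.55, and 4.85 after local shifts). Of these, 48 lay in a tandem array on chromosome 8 from 123538784 to 123622046, where 5S rRNA genes are repeated over 83.3 kb. It held 10 shared regions with folds of 6.67 to 15.0 in replicate 1 and 9.10 to 15.8 in replicate 2, so the count of genes rests on 1 array. Transcribed pseudogenes were also near shared regions more often (37.9% against 28.2%, ratio 1.35, adjusted permutation p = 0.0069, and 1.23 after local shifts). So were long non-coding RNA genes (44.8% against 39.3%, ratio 1.14, and 1.03 after local shifts). The ratios of long non-coding RNA genes were close to those of protein-coding genes (1.15, and 1.03 after local shifts).

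The classes below rotation were olfactory receptor genes and pseudogenes of immunoglobulin and T cell receptor variable segments. Of 1428 olfactory receptor genes, 25.1% had a shared region within 5 kb, against 36.6% after rotation (ratio 0.687, adjusted permutation p = 0.0069, and 0.738 after local shifts). For variable segment pseudogenes the share was 2.61% (4 of 153 genes) against 11.2% (ratio 0.233, and 0.247 after local shifts). The 394 variable segment genes that are not pseudogenes did not pass. Their share was 9.9% against 11.8% (ratio 0.841, adjusted permutation p = 0.64, and 0.871 after local shifts). Vomeronasal receptor genes had a ratio of 0.856 that did not pass (adjusted permutation p = 0.19) and 0.840 after local shifts, which did (adjusted permutation p = 0.0095).

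A candidate explanation for olfactory receptors is that reads shared between paralogs were lost, which should lower the density inside the genes more than beside them. The density was 14.3 shared regions per Mb inside the genes and 32.7 at 2 to 10 kb outside, a ratio of 0.438 (95% exact interval 0.301 to 0.617). Protein-coding genes shorter than 5 kb, without olfactory and vomeronasal receptors, had a ratio of 1.66. The olfactory receptor genes were taken by symbol whatever their gene type, so the 2 sets were not chosen alike. The flanks themselves were at 0.836 times the mean of their chromosomes, between the bounds set for a sparse neighbourhood and a normal one, so a regional effect cannot be told apart. Closed chromatin at receptor genes would give the same direction and was not tested, so loss of shared reads remains a hypothesis.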
